A study of Caenorhabditis elegans with 51 samples.

How the data were processed

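RNA from whole Caenorhabditis elegans animals was sequenced in 5 experiments that lower or alter XRN2, the nuclear 5'-3' exoribonuclease encoded by xrn-2. The series holds 51 samples, of which 35 RNA libraries were analysed. The 16 chromatin immunoprecipitation and input libraries come without tables of values and were not analysed here. Per the labels' protocols, RNA was extracted with TRI Reagent and treated with DNase, 32 libraries were made with a polyA-selecting kit (TruSeq Standard mRNA) and the 3 rRNA-depleted libraries with NuGEN Ovation Universal. The time course followed wild type (WT) and xrn-2(xe31), a temperature-sensitive strain, each hour from 0 to 10 h after a shift from 15 °C, where the animals had grown for 59 h, to 26 °C, with 1 library per strain and hour. RNA of the 6 h and 10 h animals of both strains was sequenced again more deeply, which adds reads and no new samples. A strain that carries a catalytic-dead xrn-2 transgene fused to GFP on top of xe31 was profiled at 6 h and 10 h beside its own WT. RNAi against xrn-2 or an empty vector was fed from L1 to mid-L4 at 20 °C, with 1 polyA library per treatment, and with 1 mock and 2 xrn-2 RNAi libraries depleted of rRNA.

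The values used are read counts: per the file headers, the authors deposited whole-number counts per gene, and counts in a window downstream and a window upstream of each gene, for each library. The submitters' processing notes name genome build ce10. The aligner, the counting program, the use of strand and the window lengths are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical gene copies could not be separated. Window tables list 9634 to 17429 of the 44200 genes. Symbols were found for 42362 gene IDs (95.8%). The polyA RNAi tables also hold replicates that belong to another series, and their 4 gene count columns and 8 window columns were not used. Columns of the time course, resequenced and catalytic-dead tables were assigned to strain and hour by their names.

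Gene counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation and filterByExpr at a minimum count of 10. The Benjamini-Hochberg (BH) method adjusted p-values over the genes tested, with a threshold of 0.05. The time-course model had hour as a block and a strain effect in an early (0 to 2 h), a middle (3 to 5 h) and a late (6 to 10 h) window, with 8 residual degrees of freedom. The catalytic-dead and resequenced fits had hour as a block, which left 1 residual degree of freedom, as did the rRNA-depleted fit with its single mock library. The strain difference set the catalytic-dead effect against the resequenced xe31 effect, each relative to its own WT, with 2 residual degrees of freedom. P-values measure only the spread between these libraries. The polyA pair has no test: log2 ratios with pseudocount 1 are given for genes with at least 100 counts, with exact binomial 95% intervals. Intervals of single genes and floors cover counting error only. The interval of the median polyA ratio comes from the spread between genes, taken as independent, and does not measure the spread between libraries.

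Readthrough was measured as the change of the ratio of downstream counts to whole-gene counts, in 1 edgeR model over both kinds of counts, for genes with at least 20 downstream counts and a mean of at least 10 gene counts. This departs from the design. The design written before the data were examined took the ratio of downstream to upstream counts as the main measure, on the assumption that the upstream window lies before the gene end, and listed whole-gene counts as an alternative. The files showed that the upstream window holds little of the gene's signal: its counts had a median of 0.199% to 1.35% of the gene's counts. It is taken here to lie before the gene start, which the sources used here do not state. The reference was then switched. The switch was made after the files had been looked at, and 1 reason noted at the time, that both windows rise in the mutants, was itself information on the outcome. Results with the ratio as designed differ strongly and stand beside the main ones. In those fits the mean of at least 10 counts applied to upstream counts in place of gene counts. A different set of genes was therefore tested, and the counts of genes called do not compare directly. The upstream window was also tested on its own, as an added measure.

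The 22 gene lists, the windows of hours and the rule for named genes were fixed before the data were examined. The rule took xrn-2, the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 2, and up to 3 called members per list. For readthrough it took the 15 largest rises and 5 largest falls with at least 50 downstream counts in the affected libraries. In the late window a named gene had to move the same way in all 5 hours. Lists were tested with camera at a correlation of 0.01 and again with an estimated correlation, and with fry. Fry asks whether a list's own genes changed, not whether they changed more than other genes. The microRNA list had fewer than 3 tested genes and was left out. For the polyA pair, list medians were placed among 10000 random lists matched on expression. Summed values per hour were compared with an exact two-sided sign-flip test, and correlated with hour with 100000 permutations. The planned test of same-strand neighbours could not be run as written, because the reference gene table (WBcel235) gives no strand. The gene's own upstream window and the flanking genes by order took its place, chosen after the data were seen. Where all control libraries had 0 downstream counts, the fold is a lower bound from a floor of 3 counts over the group.

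The late, rRNA-depleted, catalytic-dead, resequenced and strain difference tests of genes and readthrough were run on simulated data drawn from the real means, library sizes and dispersions, with 100 genes changed 2-fold and 100 changed 8-fold. Each gene had 1 mean over all hours and the dispersion of the trend, so hour effects and gene-to-gene spread were absent. Changed genes had a mean log2 CPM over 1, or at least 100 downstream counts for readthrough. The recoveries and false calls may therefore look better than in the real data. The late gene test recovered 100% of both, and called 10 of 16337 unchanged genes. The late readthrough test recovered 36% of 2-fold and 99% of 8-fold changes, and called 4 of 10857 unchanged genes. The catalytic-dead gene test recovered 0% and 56%, its readthrough test 3% and 64%. The resequenced gene test recovered 81% and 100%, its readthrough test 1% and 55%. The rRNA-depleted gene test recovered 1% and 81%, its readthrough test 0% and 0%. The strain difference recovered 0% and 65% for genes, and 0% and 3% for readthrough. Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, limma 3.58.1 on the log ratio with pseudocounts of 1 and 5, other count minimums, other references, fits without the hour block, hour shifts and leaving out each hour or library. Figures were drawn with matplotlib 3.10.9.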

Results

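The time-course libraries held 41238235 to 57832479 gene counts each, over 11 WT and 11 xe31 libraries. The 4 resequenced libraries (2 WT and 2 xe31) held 239213652 to 253142688, the 4 libraries of the catalytic-dead experiment (2 WT and 2 mutant) 49628394 to 74356542, the 3 rRNA-depleted libraries (1 mock and 2 xrn-2 RNAi) 21695913 to 23817072 and the 2 polyA RNAi libraries 36463650 and 44605077. The experiments ask what happens to transcript ends and to gene expression when XRN2, a nuclease linked to transcription termination, is impaired.

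The targeted gene differed between the experiments. In late xe31 libraries the xrn-2 transcript was higher, 224.9 against 113.8 CPM in WT (log2 change 0.99 ± 0.07 SE, edgeR with BH adjustment, adjusted p = 1.53e-06, n = 5 hours, higher in 5 of 5). The allele acts on the protein, so the transcript does not check the strain labels. In the catalytic-dead strain, which carries an extra xrn-2 copy, it stood at 459.9 against 118.6 CPM (log2 1.99 ± 0.29, edgeR, BH-adjusted p = 0.0537). The polyA RNAi library had 69.6 CPM against 151.2 CPM in mock (log2 -1.12, 95% interval -1.18 to -1.06). In the rRNA-depleted libraries labelled xrn-2 RNAi, xrn-2 was not detectably lower than in mock (69.5 against 79.4 CPM, log2 -0.21 ± 0.30, edgeR, BH-adjusted p = 0.915), and the directions drawn from those libraries rest on their labels.

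The first question was whether RNA extends past gene ends after the shift of xe31 to 26 °C. Between 6 and 10 h, counts downstream of genes rose relative to the genes' own counts across much of the transcriptome. Downstream counts of bcs-1, a chaperone of the mitochondrial respiratory chain, went from 0 to 1059 against 13681 and 12528 gene counts, at least 386-fold. Those of sun-1, a nuclear envelope protein of the germline, went from 0 to 1123, at least 360-fold. Those of the egg surface gene egg-1 went from 0 to 387, at least 219-fold in the ratio. The fall of its gene counts from 62494 to 36766 adds to this. The collagens col-166 and col-178 rose at least 261-fold and at least 193-fold, wdr-46 at least 176-fold and trpp-11 at least 131-fold. For hsp-4, an endoplasmic reticulum chaperone, and rpl-12, a ribosomal protein, the rises were at least 109-fold and at least 107-fold, although their downstream counts stayed at 0.128 and 0.0751 per 100 gene counts. Downstream counts of lro-1 went from 1 to 2444, of ttr-15 from 1 to 1428, of F46F2.3 from 1 to 1860, of nspe-1 from 1 to 801, of rpl-33 from 2 to 1292 and of T15B7.1 from 2 to 1484. The 5 largest falls of the ratio came with a rise of the gene counts. These were F59E12.8 (log2 -7.26 ± 0.48, gene counts 3 to 478, downstream counts 797 to 715), WBGene00020440 (-4.51 ± 0.76, 4 to 836, downstream 26 to 215), B0228.8 (-4.40 ± 0.46, 7 to 276, downstream 152 to 250), lips-13 (-4.02 ± 0.50, 35 to 613, downstream 114 to 102) and F35E2.1 (-3.997 ± 0.38, 9 to 285, downstream 969 to 1369), each with an edgeR, BH-adjusted p of 2.19e-05 or less.

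Of 11263 genes tested, 5413 rose and 276 fell in the downstream ratio (edgeR, BH), with a median log2 change of 1.07, and 1146 rose over 16-fold. Without 8 h, 178 genes fell. The window that the files call upstream, whose position is not given in the sources used here and is taken to be before the gene start, rose as well: 3505 of 8511 genes were called up and 183 down relative to library size, with a median log2 change of 0.95. The design had upstream counts as the reference, and was changed after the files had been looked at. That reference also changes which genes are tested, since the minimum mean then applies to upstream counts, so its counts do not compare directly with 5413 of 11263. With that reference, for late xe31 readthrough, genes up numbered 573 and genes down 243, with a median of 0.55. There the direction for late xe31 readthrough, col-166 turned, to -1.445 (edgeR, BH-adjusted p = 1). By list, 53 of 58 ribosomal protein genes, 18 of 18 DNA replication genes, 8 of 8 organelle chaperones, 16 of 18 oocyte genes and 82 of 127 collagens were called up, against 3 of 21 cuticulins and 38 of 116 immune effectors. Highly expressed genes were called more often: 19.8% in the lowest of 4 groups by WT expression, then 39.3%, 58.5% and 74.6%. Within 10 bins of WT expression no list differed from other genes (Mantel-Haenszel test, smallest BH-adjusted p = 0.105), while 8 of the lists differed without the bins (Fisher exact test, BH-adjusted p of 0.015 or less).

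Summed over genes, downstream counts per 100 gene counts lay between 0.886 and 1.31 in WT and rose from 0.905 at 0 h to 1.75 at 10 h in xe31. The difference on the log2 scale was positive in 11 of 11 hours (mean 0.25 ± 0.20 SD, exact sign-flip p = 0.000977, 0.00293 adjusted over the 3 summaries tested). In the 5 late hours it averaged 0.41 ± 0.20 (1.33-fold, exact p = 0.0625, the smallest that 5 pairs allow), and in the 3 early hours 0.09 ± 0.08. It grew with hour (Pearson r = 0.885, permutation p = 5e-05, adjusted 7.5e-05; Spearman rho = 0.900, permutation p = 4e-04, adjusted 6e-04; r = 0.838 without 0 h and 10 h, permutation p = 0.0022). With 1 library per strain and hour, neighbouring hours are not independent samples. The sign-flip and permutation p-values treat hours as independent and exchangeable, and do not measure how well a strain effect repeats. The summed ratio of downstream to upstream counts, as designed, showed no detectable difference: mean -0.0136 over 11 hours (exact p = 0.411, positive in 6 of 11) and -0.0009 in the late hours (exact p = 1, where 5 pairs allow no p under 0.0625).

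**Figure D1:**
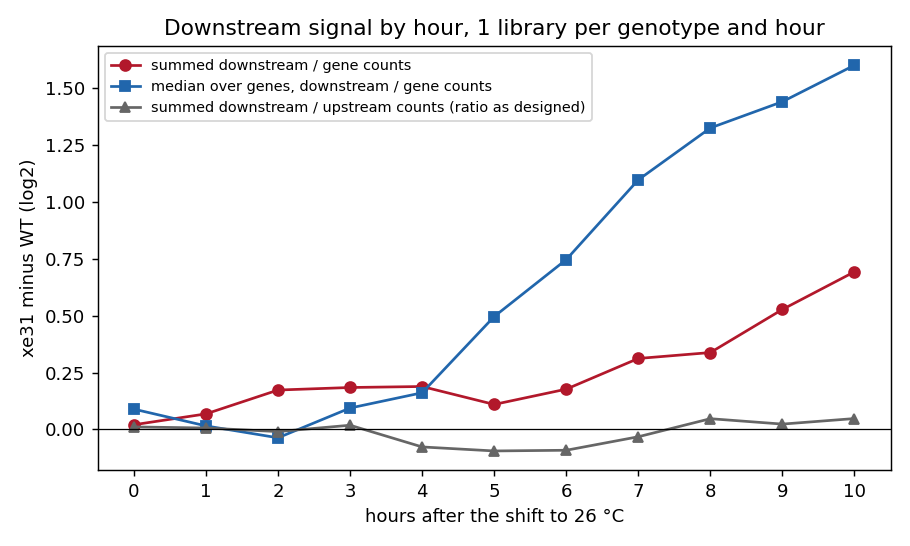
The xe31 minus WT difference on the log2 scale (vertical axis) at each hour after the shift (horizontal axis), from 1 library per strain and hour. Summed downstream over gene counts (circles) reach 0.69 at 10 h and the medians over genes (squares) average 1.24 in the late hours, while summed downstream over upstream counts (triangles) average -0.0009 there.

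Gene expression in late xe31 changed for many genes, with the larger changes upward. The largest rises were W05B2.2 (0.183 to 16.5 CPM), egas-1 (0.366 to 25.6), the cytochrome P450 gene cyp-33D3 (0.422 to 17.01), Y22D7AL.4 (0.594 to 22.1), phlp-2 (0.9503 to 23.9), the ciliary genes nphp-1 (0.760 to 19.7) and mks-5 (0.934 to 12.3), F54C9.7, F07A11.1 and the homeobox gene ceh-99 (5.44 to 88.2 CPM). Their log2 changes ran from 6.45 ± 0.55 for W05B2.2 to 3.63 ± 0.29 for mks-5, each higher in 5 of 5 hours (edgeR, BH-adjusted p of 8.47e-06 or less). Of genes over 2-fold higher with a tested upstream window, 81.0% had that window called up. Reads running in from an upstream neighbour may therefore add to these rises. Falls were smaller: cdk-5, a neuronal kinase, fell by 2.09 ± 0.21 on the log2 scale (44.0 to 10.6 CPM), T05F1.2 by 1.74 ± 0.12 and cpar-1, a centromeric histone variant, by 1.60 ± 0.19. The other large falls were pud-4, T20G5.8, H17B01.2, D1086.7 and the histone genes his-59, his-68 and his-60, with log2 changes from -1.40 to -1.28.

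Germline and growth lists lay lower by camera with the preset correlation. These calls are lost at adjusted p = 0.493 for oocyte, 0.41 for germline, 0.493 for DNA replication and 0.507 for ribosomal protein genes with an estimated correlation. Fry, which does not set a list against other genes, gave adjusted p = 0.0111, 0.00136, 0.0111 and 0.0112 for the same lists. Of 22 oocyte genes 17 fell and 0 rose (17 adjusted over the list alone), among them puf-5 (-1.11 ± 0.15), egg-1 (-0.71 ± 0.12) and the eggshell gene cbd-1 (-0.61 ± 0.11). Against WT 1 hour earlier late xe31 gene expression, cbd-1 stood at 0.001. Of 22 germline genes 15 fell (15 adjusted over the list alone), with nos-3 at -0.52 ± 0.06 and daz-1 at -0.72 ± 0.09. Of 25 DNA replication and cell cycle genes 20 fell (21 adjusted over the list alone), including the replicative helicase gene mcm-4 (-0.98 ± 0.12), mcm-10 (-0.64 ± 0.08) and cdc-6 (-0.36 ± 0.06). Of 74 ribosomal protein genes 38 fell (43 adjusted over the list alone) by small amounts, as for rpl-3 (-0.28 ± 0.04), and 11 of 18 ribosome biogenesis genes fell and 3 rose (13 and 3 adjusted over the list alone), with fib-1 at -0.22 ± 0.04. Histones fell in 12 of 23 genes and intestinal genes in 7 of 22 (12 and 7 adjusted over the list alone), including mtl-1 (-1.03 ± 0.09) and vha-6 (-0.24 ± 0.05), and muscle genes in 5 of 23 (4 adjusted over the list alone), including tni-3 (-0.22 ± 0.03). Cuticle collagens rose in 40 and fell in 14 of 160 genes (40 and 12 adjusted over the list alone), led by dpy-14 (4.61 ± 0.35, 0.394 to 11.08 CPM) and col-45 (2.39 ± 0.19). Molting genes rose in 8 and fell in 2 of 23 (9 and 2 adjusted over the list alone), with mlt-4 at 1.39 ± 0.15 and mlt-11 at 1.73 ± 0.33. Hedgehog-related genes rose in 18 and fell in 2 of 55, led by grd-8 (4.54 ± 0.39), and cuticulins rose in 10 and fell in 1 of 34, with the same counts adjusted over the list alone.

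Sperm genes rose in 26 and fell in 2 of 72 (27 and 2 adjusted over the list alone), including ssp-19 (0.70 ± 0.06) and spe-15 (0.39 ± 0.04). Against WT 1 hour later late xe31 gene expression, ssp-19 stood at -0.006. Immune effectors rose in 46 and fell in 14 of 199 (46 and 14 adjusted over the list alone), including the C-type lectins clec-161 (4.55 ± 0.24) and clec-125 (3.01 ± 0.22). Detoxification genes split, 27 up and 28 down of 176 (25 and 25 adjusted over the list alone), with gst-24 (2.37 ± 0.11) and cyp-29A4 (4.70 ± 0.23) among the rises. Genes of RNA 3'-end processing and nuclear decay rose in 6 and fell in 11 of 26 (7 and 11 adjusted over the list alone), with clpf-1, a 3'-end cleavage factor, at 1.14 ± 0.11 and xrn-1, the cytoplasmic relative of xrn-2, at 0.42 ± 0.05. Neuron genes rose in 1 and fell in 8 of 44 (0 and 1 adjusted over the list alone), pals genes rose in 4 and fell in 3 of 31, organelle chaperones rose in 1 and fell in 4 of 12, heat shock genes rose in 2 and fell in 1 of 12 and vitellogenins in 0 of 6, with the same counts adjusted over the list alone. Camera with the preset correlation called 13 of the lists in this comparison, and 0 with an estimated correlation (smallest adjusted p = 0.41 with an estimated correlation). Over all 17123 genes, 2967 rose and 3563 fell (edgeR, BH). Of these, 1277 rose and 89 fell over 2-fold. Without the hour block, for late xe31 gene expression, genes up numbered 1250 and genes down 519. With xe31 set against WT 1 hour earlier, for late xe31 gene expression, genes down numbered 1800.

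Genes that rose often had a rise in the upstream window as well. Among 617 genes that rose over 2-fold and had a tested upstream window, 500 (81.0%) had that window called up, against 1770 of 5004 genes that were not called (35.4%) and 33.7% of 1923 genes that fell. For all 1583 rises with a tested window the share was 68.7% (Fisher exact test, odds ratio 4.00, 95% interval 3.54 to 4.53). By order along the chromosome, 20.5% of 3954 genes flanked by a readthrough gene rose, against 12.5% of 1285 genes with no such neighbour (odds ratio 1.80, 1.5 to 2.18). Strand could not be used in either comparison.

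**Figure D2:**
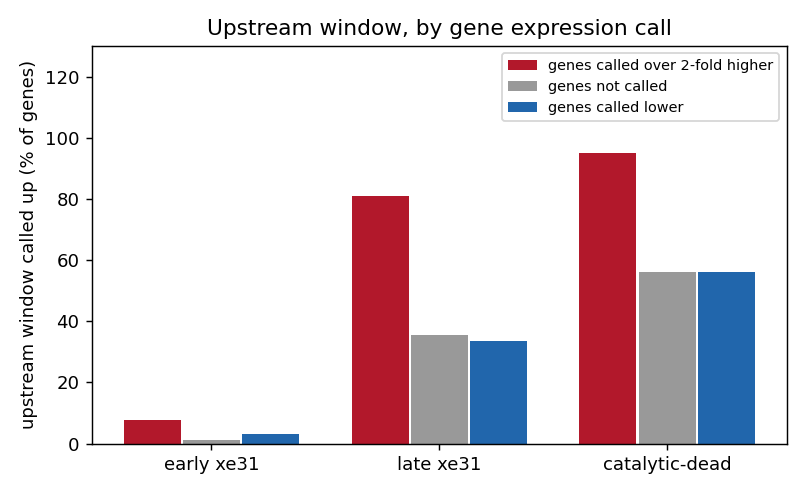
Share of genes (percent, vertical axis) whose upstream window was called up, for genes called over 2-fold higher, not called, or called lower in gene expression, in 3 comparisons. In late xe31 the shares are 81.0%, 35.4% and 33.7%, and in the catalytic-dead strain 95%, 56.1% and 56%.

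The early window shows how the strains differed within 2 h of the shift. The xrn-2 transcript was already higher (log2 0.52 ± 0.08, 143.1 to 211.1 CPM, edgeR, BH-adjusted p = 0.00193). Sperm genes stood out: 32 of 72 rose and 0 fell (41 and 0 adjusted over the list alone), with a median log2 change of 0.92 (0.89 with the 4 genes at 0 counts in WT set to their bound). The sperm phosphatases gsp-3 (0.98 ± 0.09) and gsp-4 (1.08 ± 0.10) and spe-18 (1.04 ± 0.09) doubled, and clec-123 rose by 1.00 ± 0.10. Among the largest rises were col-90 (41.9 to 263.7 CPM), nrps-1 (1.58 to 7.71), scrm-4 (3.21 to 14.3) and Y22D7AL.4 (0.351 to 2.29). Among the falls were the yolk protein genes vit-6 (-1.45 ± 0.38) and vit-1 (-1.10 ± 0.22), pud-4 (-1.23 ± 0.20), asp-17 (-1.17 ± 0.11), col-122 (-1.16 ± 0.16) and hrg-7 (-0.99 ± 0.20). Muscle genes fell in 5 of 23 (14 adjusted over the list alone), with mlc-2 at -0.28 ± 0.06, and ribosomal protein genes in 5 of 74 (0 adjusted over the list alone), with rpl-19 at -0.21 ± 0.05. Vitellogenins fell in 2 of 6 (3 adjusted over the list alone), with a median of -1.20 and a mean of 0.07. Camera called 10 lists with the preset correlation, sperm (adjusted p = 8.63e-18) and ribosomal proteins first, and 0 with an estimated correlation (adjusted p = 0.161 for sperm and 0.324 for ribosomal proteins, each with an estimated correlation). Fry gave adjusted p = 0.00409 for sperm and 0.0814 for ribosomal proteins. In all, 1142 genes rose and 174 fell of 17123 (edgeR, BH). Without 2 h, for early xe31 gene expression, genes up numbered 578 and genes down 33. Without 1 h they were 718 and 40, and without 0 h 95 fell. Against WT 1 hour later, for early xe31 gene expression, genes down numbered 826 and genes up 496, and gsp-3, gsp-4 and spe-18 stood at -0.36, -0.34 and -0.35, and early xe31 gene expression, clec-123 stood at -0.38. Against WT 1 hour earlier early xe31 gene expression, col-122 stood at 0.62.

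Fewer readthrough genes were called early on: 99 rose and 8 fell of 11263 (638 up and 241 down at an unadjusted p under 0.05), with a median log2 change of 0.07. On log ratios with pseudocount 1 the medians were 0.00, -0.02 and -0.01 at 0, 1 and 2 h, and limma gave medians of 0.01 and -0.04 at pseudocounts 1 and 5. With upstream counts as the reference, as designed, for early xe31 readthrough, genes up numbered 17 and genes down 6, and the early xe31 readthrough, median log2 change was 0.00053. Only 12.2% of genes had an interval that stayed within 2-fold in both directions, and no simulation was run for this window. In the upstream window 129 genes rose and 0 fell (edgeR, BH, 558 up and 72 down at an unadjusted p under 0.05; no other tool was run on the windows). Without 2 h 23 genes rose and 1 fell in readthrough, without 1 h 36 and 1, and without 0 h 4 fell. Downstream counts of fipr-2 went from 0 to 137 (at least 44.3-fold), of crt-1, the calreticulin gene, from 1 to 295 and of the germline helicase gene glh-2 from 2 to 189. The ratio of F59E12.8 again fell (-4.48 ± 0.81) as its gene counts went from 2 to 64. The late effect exceeded the early one in readthrough for 1057 genes and lay below it for 49 (edgeR, BH). For gene expression the late effect was higher for 977 genes and lower for 2274. Without 2 h, for late minus early readthrough, genes up numbered 452 and genes down 10. Also without 2 h, for late minus early gene expression, genes up numbered 440, and for late minus early gene expression, genes down numbered 1052. Without 0 h the counts were 518 and 19 for readthrough and 643 and 1458 for expression, and without 1 h 510 and 18, and 493 and 1056. Without 6, 8 or 9 h 90, 30 or 27 genes lay below in readthrough. Limma on the log ratio gave 2891 and 115 for readthrough, and upstream counts as the reference gave 82 and 29.

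The strain with catalytic-dead XRN2 on top of xe31 was compared with its own WT. This comparison cannot part the loss of nuclease activity from xe31, the extra xrn-2 copy or the strain's background. The catalytic-dead libraries had 2.93 and 4.08 downstream counts per 100 gene counts at 6 h and 10 h, against 1.24 and 1.11 in their WT. Downstream counts of ttr-15 went from 0 to 4676 with gene counts of 60753 and 60823, at least 1557-fold, and those of the potassium channel gene twk-5 from 0 to 2112, at least 621-fold. For nspe-1, gpdh-1 and T05B9.1 the rises were at least 766-fold, at least 1637-fold and at least 558-fold, while gene counts fell from 1658 to 836, from 12823 to 2692 and from 23255 to 8439. Downstream counts of vit-5 and col-20 went from 1 to 169 and from 2 to 391 as their gene counts fell from 62139 to 50 and from 320012 to 3768, so that the fall of the genes adds to the rise of their ratios. With upstream counts as the reference both directions turned, with catalytic-dead readthrough, vit-5 at -1.47 and catalytic-dead readthrough, col-20 at -3.26. The ratio fell in srh-76 (-10.92 ± 0.71) and zeel-1 (-8.62 ± 0.82), whose gene counts rose from 8 to 265 and from 13 to 1243. In all, 5085 genes rose and 207 fell of 10972 (edgeR, BH), with a median log2 change of 2.40 (1.90 at 6 h and 2.09 at 10 h on log ratios with pseudocount 1). Among genes that changed less than 1.5-fold themselves, for catalytic-dead readthrough, genes up numbered 2248 and genes down 15, with a median of 2.84. The upstream window rose in 4248 of 7505 genes. With upstream counts as the reference, as designed, 589 genes rose and 480 fell, with a median of 0.11. Sperm genes were called in 36 of 47 and differed from other genes within 10 bins of expression (Mantel-Haenszel test, BH-adjusted p = 0.0171). The expression of this list fell by a median of 3.26 on the log2 scale, which raises its ratio and which the bins do not remove.

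In the catalytic-dead strain, genes called lower included 4 yolk, 7 oocyte and 16 collagen genes, and genes called higher included 7 molting and 12 collagen genes. Camera called 11 lists with the preset correlation, and 0 with an estimated correlation (smallest adjusted p = 0.789 with an estimated correlation). The yolk protein genes fell to near 0: vit-6 from 12700 to 10.1 CPM (log2 -10.20 ± 0.37), vit-2 from 11060 to 15.9 (-9.37 ± 0.34), vit-5 from 657.7 to 0.419 (-10.24 ± 0.62) and vit-4 from 172.1 to 0.109 CPM. The collagen col-19, a marker of the adult cuticle, went from 2516 to 4.06 CPM (-9.43 ± 0.53), col-122 from 2556 to 3.67 and col-179 from 234.2 to 0.277. Vitellogenins fell in 4 of 6 (6 adjusted over the list alone). Of 22 oocyte genes 7 fell (22 adjusted over the list alone), among them perm-4 (-3.47 ± 0.30), perm-2 (-3.84 ± 0.35) and puf-11 (-4.17 ± 0.41), and of 72 sperm genes 1 fell, ssp-19 (-6.07 ± 0.71), with 47 down and 1 up adjusted over the list alone. Germline genes had a median of -0.70 (0 of 22 called, 9 lower adjusted over the list alone), DNA replication genes -1.43 (0 of 25 called, 12 lower) and neuron genes 0.75 (0 of 44 called, 0 adjusted over the list alone). Molting genes rose in 7 of 23 (13 up and 1 down adjusted over the list alone), with noah-1 going from 11.13 to 413.3 CPM, acn-1 from 11.7 to 318.8 and mlt-11 from 4.39 to 357.5. Hedgehog-related genes rose in 4 of 51 (20 adjusted over the list alone), including wrt-10 (6.09 ± 0.39), wrt-1 (4.37 ± 0.42) and qua-1 (4.73 ± 0.52). Collagens went both ways, 12 up and 16 down of 160 (46 and 25 adjusted over the list alone). The lysozyme gene lys-7 (33.4 to 799.5 CPM) and clec-52 rose, cyp-33D3 rose (0.263 to 31.8 CPM) and ugt-63 fell (123.4 to 2.35 CPM). ZK355.3 had 0.00727 CPM in WT and 18.8 in the mutant, and F33D11.6, srw-73 and clec-11 had 0.0189 CPM in WT and 19.1, 15.6 and 10.9 CPM in the mutant. In all, 120 genes rose and 80 fell of 17212 (edgeR, BH). Of 80 rises with a tested upstream window, 76 (95%) had that window called up. The share was 56.1% among genes not called and 56% among genes that fell. Reads running in from upstream may therefore add to these rises. With DESeq2, for catalytic-dead gene expression, genes up numbered 2100 and, for catalytic-dead gene expression, genes down numbered 1660. EdgeR without the hour block called 1889 and 601.

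Single libraries were matched to the WT hours over the 2000 genes most variable in the WT time course. The catalytic-dead library of 6 h correlated best with WT at 1 h (r = 0.827 across genes, against 0.198 at 6 h) and that of 10 h with WT at 3 h (0.610, against 0.174 at 10 h). The latter match was nearly equal at 4 h (0.607). The WT libraries of that experiment matched 7 h and 10 h, and xe31 libraries matched their own hour except at 4 h and 5 h, which matched 5 h and 6 h. Genes are not independent replicates, and these values describe the libraries.

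**Figure D3:**
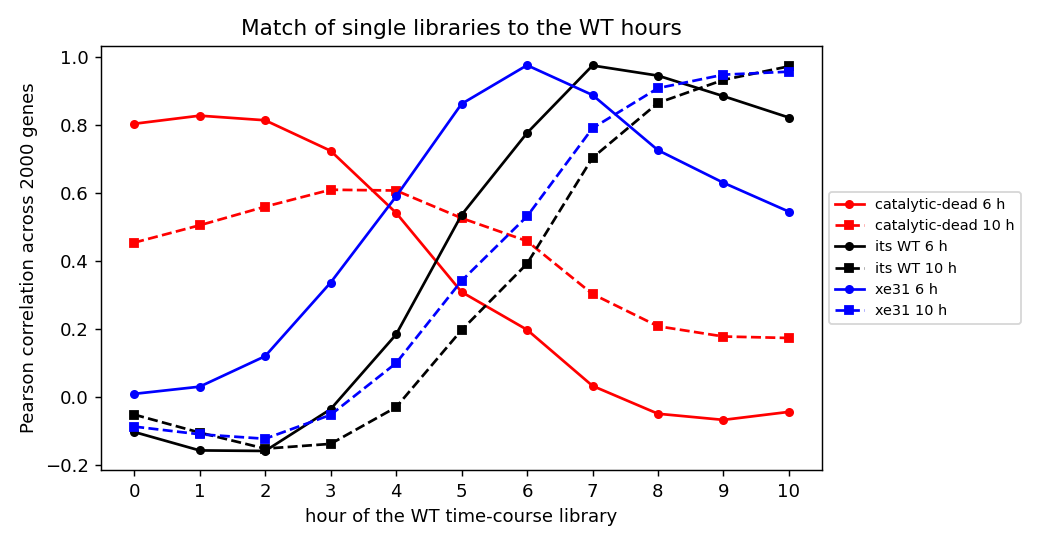
Pearson correlation across 2000 genes (vertical axis) of 6 single libraries with the WT library of each hour (horizontal axis). The catalytic-dead libraries of 6 h and 10 h peak at WT 1 h (0.827) and 3 h (0.610), and xe31 at 6 h and 10 h peaks at its own hour.

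Set against the resequenced xe31 effect, the catalytic-dead effect differed in 12 genes, 1 higher and 11 lower of 18925 (edgeR, BH). The neuronal immunoglobulin gene zig-4 was higher by 7.63 ± 0.32 on the log2 scale. The yolk genes vit-6 (-10.16 ± 0.30) and vit-2 (-9.29 ± 0.27), the collagens col-179, col-19, col-122, col-184, col-119, col-106 and col-80 (from -9.50 to -7.52) and F02E8.4 (-8.40 ± 0.33) were lower, as was F08H9.2, which lies outside the rule and was named after its value was seen. Sperm genes had a median of -3.62 (0 of 72 called, 48 lower adjusted over the list alone) and molting genes one of 2.74 (0 of 23 called, 11 higher and 1 lower adjusted over the list alone). Camera called 13 lists here, and 0 with an estimated correlation (smallest adjusted p = 0.632 with an estimated correlation). With DESeq2, for strain difference gene expression, genes up numbered 1317 and, for strain difference gene expression, genes down numbered 1341. The edgeR test called 0 genes without either resequenced pair, 2419 and 2254 without the catalytic-dead pair of 6 h and 1598 and 2392 without that of 10 h. For readthrough edgeR called 0 of 13808 genes (1513 up and 321 down at an unadjusted p under 0.05; limma called 0), with a median of 0.87. With upstream counts as the reference, as designed, 29 genes were called higher and 27 lower. Among 3589 genes that changed less than 1.5-fold in both, the median log2 change was 2.86 in the catalytic-dead strain and 1.49 in xe31.

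The resequenced libraries repeat the 6 h and 10 h RNA at greater depth. No gene passed in edgeR among 18213 for gene expression (1581 up and 518 down at an unadjusted p under 0.05; with DESeq2, for resequenced xe31 gene expression, genes up numbered 1339 and, for resequenced xe31 gene expression, genes down numbered 1231) or among 13419 for readthrough (4033 up and 150 down at an unadjusted p under 0.05; limma, for resequenced xe31 readthrough, genes up: 448, and down: 57). The median readthrough change was 1.10 (0.63 at 6 h and 1.45 at 10 h), and the upstream window rose in 2569 and fell in 4 of 10638 genes. With upstream counts as the reference 1004 genes rose and, for resequenced xe31 readthrough, genes down numbered 766. Camera called 13 lists, and 0 with an estimated correlation.

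The rRNA-depleted libraries ask the same of RNA that was not selected for polyA tails. Downstream counts per 100 gene counts were 6.00 and 5.404 in the libraries labelled xrn-2 RNAi against 3.81 in mock. The median readthrough change over 7038 genes was 0.32 (0.35 and 0.29 in the 2 libraries). EdgeR called 0 genes for readthrough (1130 up and 324 down at an unadjusted p under 0.05; limma called 0), in a design in which the simulated data gave 0 calls, and 0 of 15917 for gene expression (1488 and 847 at an unadjusted p under 0.05; with DESeq2, for rRNA-depleted RNAi gene expression, genes up numbered 743 and genes down 361). With upstream counts as the reference 52 genes rose and 22 fell in readthrough. The upstream window was called higher in 496 and lower in 96 of 4877 genes, against a single mock library and with 1 residual degree of freedom. Vitellogenins had a median log2 change of -4.31 (0 of 6 called, 5 lower adjusted over the list alone), molting genes 2.23 (0 of 23 called, 11 higher and 2 lower adjusted over the list alone), hedgehog-related genes 2.29 (0 of 44 called, 21 and 5 adjusted over the list alone) and pals genes, a family induced by intracellular infection, 4.43 (0 of 33 called, 0 adjusted over the list alone). Camera called 11 lists, and 0 with an estimated correlation (smallest adjusted p = 0.74 with an estimated correlation). In mock the 20 most abundant genes took 35.0% of the counts, against 27.1% and 28.1%. Across genes the expression changes ran against the WT change from 0 to 2 h to 8 to 10 h (Spearman rho = -0.244). A difference of developmental stage from mock was not tested.

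The polyA RNAi pair has 1 library per treatment and no replicate check. Downstream counts per 100 gene counts were 1.97 after xrn-2 RNAi and 1.05 in mock. The ratio had a median log2 change of 0.82 over 1702 genes, 791 over 2-fold higher and 140 lower. The 95% interval of this median, 0.69 to 0.95, covers the spread between genes only and not the precision of the treatment effect. Downstream counts of pssy-2, pir-1, exo-3 and rps-16 went from 0 to 534, 613, 249 and 387, at least 169-fold, at least 96.5-fold, at least 93.6-fold and at least 96.3-fold. Vitellogenins had a median of -8.71 (lowest of 10000 random lists matched on expression), oocyte genes -2.16 (also lowest), germline genes -0.99 (also lowest), cuticle collagens -0.88 (also lowest, with 62 over 2-fold lower and 44 higher), DNA replication genes -0.73 (percentile 0.02), intestinal genes -0.84 (percentile 0.05), molting genes 3.19 (highest), hedgehog-related genes 1.97 (highest), cuticulins 1.65 (highest), neuron genes 0.81 (highest) and pals genes 1.85 (percentile 99.98). Sperm genes had a median of -0.30 (percentile 0.45). The random lists were drawn gene by gene and do not keep the correlation within a list. Lists whose genes move together therefore reach extreme percentiles more easily. Gene counts of col-19 went from 84794 to 72 (log2 -10.86, -11.23 to -10.55), of vit-5 from 32699 to 36 and of ZK813.1 from 2013 to 0, at least 1073-fold lower. Those of clc-32 went from 0 to 2194, at least 457-fold, of C25F9.12 from 0 to 1355, at least 282-fold, of egas-2 from 0 to 1077, at least 224-fold, and of srsx-35 from 2 to 4300 (log2 9.81, 8.54 to 13.44). Of 13970 genes, 2365 were over 2-fold higher and 1614 over 2-fold lower. Across genes these expression changes ran against the WT change from 0 to 2 h to 8 to 10 h (Spearman rho = -0.441). They went with the changes of the catalytic-dead strain (rho = 0.652). Whether developmental stage differed between RNAi and mock was not tested, so the list changes may reflect stage.

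Readthrough genes overlapped between experiments with separate controls. Among 9545 genes tested in both, 4822 rose in late xe31 and 4610 in the catalytic-dead strain, and 3639 rose in both, where independent lists would share 2329 (Fisher exact test, odds ratio 11.9, 95% interval 10.8 to 13.1). Late xe31 called highly expressed genes more often, which the odds ratio does not remove. Call rates by expression were not computed for the catalytic-dead strain. Across genes the changes in late xe31 correlated with those in the catalytic-dead strain (Spearman rho = 0.735), after polyA RNAi (0.663) and in the rRNA-depleted libraries (0.360), among 10 pairs of experiments compared. The catalytic-dead strain also contains xe31, so that comparison shares an allele.

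**Figure D4:**
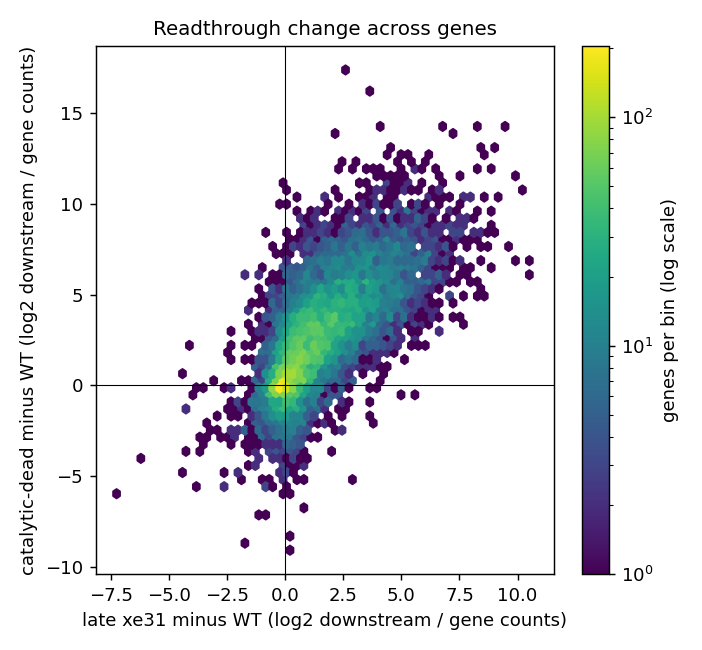
Each bin holds genes placed by the log2 change of downstream over gene counts in late xe31 (horizontal axis) and in the catalytic-dead strain (vertical axis), shaded by the number of genes on a log scale. The changes correlate across genes (Spearman rho = 0.735, 9545 genes).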

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

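The tests of split samples, the differences between windows of hours and between strains were planned, and the tests of the upstream window, of hour matching and of WT libraries were chosen only after the results were seen. Effects that differed between groups stand out here because the difference itself was tested with edgeR and BH adjustment. The late effect of xe31 differed from the early one in gene expression (977 genes higher and 2274 lower), in readthrough (1057 and 49) and in the upstream window (558 and 77). The catalytic-dead effect differed from the xe31 effect in gene expression (1 gene higher and 11 lower) and in the upstream window (260 and 54). The genes are zig-4 (log2 difference 7.63), vit-6 (-10.16), vit-2 (-9.29), col-179 (-9.50), col-19 (-9.34), col-122 (-9.14), col-184 (-8.885), col-119 (-8.52), F02E8.4 (-8.40), col-106 (-8.04), col-80 (-7.52) and F08H9.2 (-5.25). Without either resequenced pair the strain comparison called 0 genes. Without a catalytic-dead pair, for strain difference gene expression, genes up numbered 2419 (without 6 h) or 1598 (without 10 h) and, for strain difference gene expression, genes down numbered 2254 or 2392. The late minus early counts also depend on single hours: without 2 h, for late minus early gene expression, genes up numbered 440 and, for late minus early gene expression, genes down numbered 1052, and for late minus early readthrough, genes up numbered 452. Without 0 h these were 643, 1458 and 518, and without 1 h 493, 1056 and 510. For late minus early readthrough, genes down numbered 10, 19 and 18 without 2, 0 and 1 h, and 90, 30 and 27 without 6, 8 and 9 h.

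The 22 time-course libraries were also split in 100 ways, the real split included, and for each result only 1 split, the real one, gave as many called genes. These splits ignore the hours, and one that does not part the hours as the strains do loses its effect to the hour block. Exchanging the strains within the 5 late or 3 early hours allows too few groupings for a share under 0.05, so these splits do not exclude chance for the late and early results, and such exchanges were not run for late minus early. Late gene expression had 6530 called genes against 5604 in the highest other split, early gene expression 1316 against 960, and late minus early gene expression 3251 against 1430. For readthrough, counted with limma, the values were 5535 against 5273 late, 112 against 1 early and 3006 against 2369 for late minus early. The median of the other splits was 0. The highest other splits of the late results part 4 of the 5 late hours as the strains do, which is the real grouping in large part.

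The expression changes of the catalytic-dead strain (120 genes called higher and 80 lower with edgeR, BH) were weighed against 2 explanations. A candidate explanation is development behind that of WT. Its libraries matched WT hours 5 h and 7 h earlier than their own (offsets of -5 and -7), while the WT libraries of the same experiment matched 7 h and 10 h. The offset of -7 is not precise, since the 10 h library correlated at 0.610 with WT 3 h and 0.607 with WT 4 h. The 120 and 80 genes were called against WT of the same experiment, so a batch difference between the experiments bears only on the strain difference. Over the 12 genes that differ between the strains, the WT libraries had a median absolute log2 difference of 0.458. This argues against a batch difference for those 12 genes only. At 6 h 5 of the 12 differed by over 1 (col-119 2.22, col-80 1.47, col-179 1.35, vit-2 1.17 and col-19 1.15), below their strain differences of -8.52, -7.52, -9.50, -9.29 and -9.34, and at 10 h the largest was col-80 at -0.74. A changed share of tissues, and whether a delay follows from the loss of XRN2 activity or from the strain's background, were not tested. Reads running in from upstream may also add to the rises, since 95% of those with a tested upstream window had it called up.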

How the results depend on the processing

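Libraries of the same hour were paired in the sign-flip tests and through the hour block. With replicate numbers in place of hours no paired analysis was possible because GEO's labels give 2 or more numbers shared by groups only to libraries not analysed here, and the polyA RNAi pair shares 1 number and has no test. P-value tests could not be fitted for gene expression in the rRNA-depleted, catalytic-dead and resequenced experiments after leaving out a library. Readthrough depends strongly on the reference of its ratio: upstream counts, the measure of the design, were replaced by whole-gene counts after the files had been looked at. The 2 references also test different sets of genes, so part of the difference in counts can come from the genes tested. Alternatives with genes changed less than 1.5-fold, at least 100 upstream counts, shifted hours in the early window and left-out hours outside the late window were chosen after seeing the data. Of 1026 values for single genes outside readthrough, 943 had the same outcome, 70 lost the call, 6 gained one and 7 reversed. For single readthrough genes 402 of 413 had the same outcome, 8 lost the call and 3 reversed. The same outcome includes genes called in neither fit. It also includes left-out libraries of the rRNA-depleted and catalytic-dead experiments, judged on direction alone. Over fits with p-values, 35 of 48 late and 5 of 18 early genes for expression had the same outcome throughout.

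In late xe31 gene expression, genes up numbered 1250 without the hour block, and in late xe31 gene expression, genes down numbered 519 without it and 1800 against WT 1 hour earlier. For late xe31 gene expression, ssp-19 stood at -0.01 (-0.006) against WT 1 hour later, and for late xe31 gene expression, cbd-1 stood at 0.00 (0.001) against WT 1 hour earlier. In late xe31 readthrough, genes up numbered 3549 with at least 100 downstream counts and 573 with upstream counts as the reference. In late xe31 readthrough, genes down numbered 590 with limma at pseudocount 5, 150 among genes changed less than 1.5-fold, 144 without the hour block, 178 without 8 h and 318 without 6 h. The late xe31 readthrough, median log2 change was 0.47 with limma at pseudocount 5, 0.55 with upstream counts and 1.35 for a linear change at 10 h. In late xe31 readthrough, col-166 stood at -1.445 with upstream counts.

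In early xe31 gene expression, genes up numbered 496 against WT 1 hour later, 578 without 2 h and 1063 without 0 h. In early xe31 gene expression, genes down numbered 416 against WT 1 hour earlier, 826 against WT 1 hour later, 33 without 2 h and 95 without 0 h. Single genes were col-122 at 0.62 against WT 1 hour earlier, and spe-18 at -0.35 (-0.346), gsp-3 at -0.36 (-0.362), gsp-4 at -0.335 and clec-123 at -0.38 (-0.376) against WT 1 hour later, from early xe31 gene expression, spe-18; early xe31 gene expression, gsp-3; early xe31 gene expression, gsp-4; early xe31 gene expression, clec-123 and early xe31 gene expression, col-122. In early xe31 readthrough, genes up numbered 63 with limma at pseudocount 5, 17 with upstream counts, 57 and 182 against WT 1 hour earlier and later, 23 without 2 h and 68 without 0 h. In early xe31 readthrough, genes down numbered 26 and 81 with limma at pseudocounts 1 and 5, 1 among genes changed less than 1.5-fold, 30 and 40 against WT 1 hour earlier and later, 1 without 1 h and 4 without 0 h. The early xe31 readthrough, median log2 change was 0.0149 and -0.0370 with limma at pseudocounts 1 and 5, 0.0552 with at least 5 counts, 0.00053 with upstream counts, 0.111 among genes changed less than 1.5-fold, 0.0316 and 0.168 against WT 1 hour earlier and later, 0.0553 without 2 h and 0.0758 without 0 h.

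In late minus early gene expression, genes up numbered 440 without 2 h and 1352 without 6 h, and in late minus early gene expression, genes down numbered 1052 and 2843. In late minus early readthrough, genes up numbered 2891 and 3653 with limma at pseudocounts 1 and 5, 82 with upstream counts, 452 without 2 h and 1499 without 6 h. In late minus early readthrough, genes down numbered 115 and 249 with limma, 29 with upstream counts, 21 among genes changed less than 1.5-fold, 10 without 2 h and 90 without 6 h. In rRNA-depleted RNAi gene expression, genes up numbered 743 with DESeq2, and in rRNA-depleted RNAi gene expression, genes down numbered 361. In rRNA-depleted RNAi readthrough upstream counts gave 52 up and 22 down, and the rRNA-depleted RNAi readthrough, median log2 change was 0.24 with limma at pseudocount 5 and 0.20 with upstream counts.

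In catalytic-dead gene expression, genes up numbered 2100 with DESeq2, 897 with RLE, 812 without the filter and 1889 without the hour block, and in catalytic-dead gene expression, genes down numbered 1660, 442, 410 and 601. In catalytic-dead readthrough, genes up numbered 2991 with at least 100 counts, 589 with upstream counts and 2248 among genes changed less than 1.5-fold. In catalytic-dead readthrough, genes down numbered 319 and 476 with limma at pseudocounts 1 and 5, 126 with at least 100 counts, 480 with upstream counts and 15 among genes changed less than 1.5-fold. The catalytic-dead readthrough, median log2 change was 2.03 and 1.35 with limma at pseudocounts 1 and 5, 2.60 with at least 100 counts, 0.11 with upstream counts, 2.84 among genes changed less than 1.5-fold, 1.90 without 10 h and 2.09 without 6 h. With upstream counts, catalytic-dead readthrough, vit-5 stood at -1.47 and catalytic-dead readthrough, col-20 at -3.26. In resequenced xe31 gene expression, genes up numbered 1339 with DESeq2 and 152 without the filter, and in resequenced xe31 gene expression, genes down numbered 1231 and 3. In resequenced xe31 readthrough, genes up numbered 448 and 627 with limma at pseudocounts 1 and 5 and 1004 with upstream counts, and in resequenced xe31 readthrough, genes down numbered 57, 97 and 766. The resequenced xe31 readthrough, median log2 change was 0.24 with upstream counts.

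In strain difference gene expression, genes up numbered 1317 with DESeq2, 19 without the filter, 0 without the resequenced 6 h pair and 2419 without the catalytic-dead 6 h pair. In strain difference gene expression, genes down numbered 1341, 44, 0 and, without the catalytic-dead 10 h pair, 2392. Without a catalytic-dead pair the spread comes from the resequenced libraries alone. With upstream counts strain difference readthrough had 29 up and 27 down. With at least 100 upstream counts, late xe31 upstream window, genes up numbered 1920, early xe31 upstream window, genes down 1, rRNA-depleted RNAi upstream window, genes up 230 and down 51, and catalytic-dead upstream window, genes up 1907. The summed downstream share by hour was -0.0136 as downstream over upstream counts and 0.64 as the median over genes. The polyA RNAi readthrough, median log2 change was 1.05 and 0.55 with at least 50 and 200 counts and 0.69 with pseudocount 5, and the polyA RNAi readthrough, percent over 2-fold up was 50.7, 36.96 and 43.2. The polyA RNAi gene expression, percent over 2-fold up was 18.6 and 15.1 with at least 50 and 200 counts. With an estimated correlation 0 gene lists were called in late xe31 (13 with the preset correlation), early xe31 (10), late minus early (11), rRNA-depleted RNAi (11), catalytic-dead (11), resequenced xe31 (13) and the strain difference (13). The smallest adjusted p by fry was 0.00136 in late xe31, 0.00409 in early xe31 and 0.00344 in late minus early. It was 0.353 in rRNA-depleted RNAi, 0.242 in catalytic-dead, 0.593 in resequenced xe31 and 0.108 in the strain difference. The overlap of late and catalytic-dead readthrough genes was 1960 at a threshold of 0.01.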

Other observations

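The tests of upstream windows and the shift of hours in the early window were chosen only after the results were seen, while the shift of hours in the late window and the ratio of downstream to upstream counts were planned. The genes over 2-fold higher in late xe31 were weighed against 2 technical explanations. Reads running in from an upstream neighbour may explain part of them: 81.0% of the 617 genes with a tested upstream window had it called up, against 35.4% of genes not called. The other genes among the 1277 have no tested window, and a general rise of signal outside genes stays open. This reading rests on the upstream window lying before the gene start, which the sources used here do not state. A mismatch of developmental time as the whole cause was argued against, since 1138 genes were called over 2-fold higher against WT 1 hour earlier (1003 of the 1277 among them) and 1561 against WT 1 hour later (1040 among them).

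The rise of sperm genes in early xe31 may come from xe31 being ahead in developmental time. The list's median was 0.92, and it was -0.33 against WT 1 hour later and 2.25 against WT 1 hour earlier, so a lead of less than 1 hour and a strain effect cannot be told apart with hourly samples. Other early changes are mixed. The genes vit-6 (-1.45) and col-122 (-1.16), far more abundant in later WT libraries, were lower, which a lead alone would not give. Across genes the early changes went with the WT change from 0 to 2 h to 8 to 10 h (Spearman rho = 0.358). Of 25 called sperm genes with a tested upstream window, 1 (4%) had it called up, against 1.21% of genes not called. That test called 129 of 8511 windows up and was not simulated for the early hours. It therefore cannot decide whether reads running in from upstream add to the rise.

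Summed over genes, the ratio of downstream to upstream counts had a mean log2 difference of -0.0009 in late xe31 (exact sign-flip p = 1, 5 hours, where the smallest possible p is 0.0625). Gene by gene the same ratio leaned upward: in late xe31 readthrough, genes up numbered 573 and genes down 243, with a median of 0.55. Whether the rise is specific to the region past the gene end stays open.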
